A study of Homo sapiens with 6 samples.

How the data were processed

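The data are RNA-seq expression values from human umbilical vein endothelial cells (HUVECs), primary cells from the lining of the umbilical vein. Per the labels' protocols, cells plated at 50000 cells per ml were transfected with 50 nM of a miR-409-3p mimic or of a non-specific control, and were given 100 µM sodium palmitate for 16 h before RNA was taken. A mimic is a synthetic small RNA that supplies extra copies of a microRNA, and palmitate is a saturated fatty acid. RNA was taken 48 h after transfection, per the labels. Each group has 3 libraries, so 6 libraries were analysed. The labels call them biological replicates 1 to 3 and do not say whether they came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

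Per the labels' protocols and the series' design text, mRNA was enriched from 500 ng of total RNA, fragmented, made into libraries with 13 cycles of PCR, and sequenced as single-end reads of 75 nt. Per the same text, 4 technical replicates were pooled for each sample. The submitters' processing notes name the genome builds hg38 and GRCh38.p13. The aligner, the counting tool, the annotation release and the use of strand are not given in the sources used here. The values the authors deposited are in TPM, a length-scaled share of the transcripts in a library, per the file headers, with 1 value per Ensembl gene and library, and the values of each library sum to the same total. TPM divides the reads of a gene by a gene length and rescales each library to the same total, so a TPM value is a share of the library, and a rise in a few abundant genes lowers the share of all others. Of 45372 gene identifiers, 31739 were given a symbol from a table of gene names, 13633 were not, and 43348 are in GENCODE 29, the annotation that supplied positions, exonic lengths and 3′ UTRs on GRCh38.

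TPM keeps no read total, so the depth of each library is unknown. Relative depth was read from low values: for a gene under 0.3 TPM in both control 1 and another library, the values step in whole multiples of what 1 read is worth, and the ratio most often seen between the libraries gives their ratio of reads per unit of length. Against control 1, set to 1, the relative depths were 1.4 and 1.44 for control 2 and 3, and 1.35, 1.06 and 1.12 for mimic 1, 2 and 3. After that ratio was removed, between 89.7% and 92.2% of low genes gave ratios of whole numbers up to 10, within a tolerance of 0.001. A limit of 1.2 put control 2, control 3 and mimic 1 in a deeper class and control 1, mimic 2 and mimic 3 in a shallower class. These classes come from the data, not from the labels, and within-class values rest on 3 libraries, with a single library in one of the groups, and have no error. No intervals or floors that need read counts are given.

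The test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(TPM + 1), with 2 groups and no other term, over the 13537 genes with a mean of at least 1 TPM over the 6 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, mimic minus control, which understates the change of genes at low levels; ± beside a log2 fold change is its standard error, and ± beside a TPM value is the SD over 3 libraries. The design fixed in advance foresaw normalized values and named this test for them. No step used read counts.

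The design, the tests, the alternatives and the gene lists below were chosen before the data were examined, except where an alternative is said to have been added. The genes named follow a fixed rule: DNAJB9, MAPK14, MAP4K3, ZEB1 and PGF by name; the 12 largest calls in each direction among genes with non-overlapping groups and a mean above the median of the tested genes (19.7 TPM), or, as none passed, the 10 of smallest p in each direction among these genes, given as values; and up to 4 members of smallest p from each list. XIST, Y-linked genes and identifiers without a gene symbol were left out of the genes named by size or p. Not all genes that this rule names are reported here. Other genes named, further members of the lists included, were chosen after their values were seen.

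The 22 lists were ER chaperones and ATF6/XBP1 targets, the ATF4/CHOP integrated stress response, the p38 MAPK pathway, angiogenesis and tip cell genes, endothelial identity, endothelial inflammatory activation, the interferon response, cell cycle and proliferation, p53 targets and apoptosis, fatty acid handling, cholesterol synthesis and SREBP2, NRF2 and oxidative stress, autophagy and lysosome, endothelial-mesenchymal transition, vasomotor and haemostasis, small-RNA machinery, ribosomal proteins, mitochondrially encoded genes, and markers of lymphatic endothelium, of smooth muscle, pericytes and fibroblasts, of blood cells, and of epithelium and trophoblast. A list was tested with camera in limma, which compares its members with all other tested genes, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 21 lists with at least 5 tested members. The blood cell list had 1 tested member and was not tested. Camera with an estimated correlation and fry, which asks whether the members move on balance in one direction, were run beside it. Adjusted p-values over the members of each list alone were also computed. List medians are given relative to the median log2 fold change of all tested genes, 0.087. A list score per library, the median deviation of its members from their gene means less that of all tested genes, was compared between groups by an exact two-sided permutation test over the 10 splits of 6 libraries, which cannot give a p under 0.1.

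Sites of miR-409-3p were searched in the longest annotated 3′ UTR of each gene. The mature sequence GAAUGUUGCUCGGUGAACCCCU was taken from general knowledge of the microRNA. The sources used here do not give the sequence of the mimic itself. Positions 2 to 8 pair with CAACATT (a 7mer-m8 site), CAACATTA is the 8mer site and AACATTA the 7mer-A1 site. The shift is the median log2 fold change of the 1553 tested genes with an 8mer or 7mer-m8 site minus that of the 9143 with no 8mer, 7mer-m8 or 7mer-A1 site. It was also computed within 20 bins of 3′ UTR length and set against 14105 other 7-mers, each found in at least 200 genes. Genes are not independent replicates, so these percentiles describe these libraries. A bootstrap over genes with 1000 draws gave the 95% interval of the shift.

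The alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a filter at 10 TPM, median-ratio scaling, quantile normalization, the replicate number as a block, library quality weights, leaving out each library in turn, the other list tests, and for the site shift 8mer sites alone, the shortest annotated 3′ UTR and matching on 3′ UTR length. Added after the data were seen were the depth class as a term, removal of each library's trend on exonic length or on transcript GC content (lowess, span 0.3), and rescaling without genes of a mean above 1000 TPM.

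The limma step was tested on simulated data with the 13537 genes and the spread of these libraries: of 100 genes changed by log2 0.5 it recovered 70%, of 100 changed by log2 1 it recovered 94%, and it made 6 false calls. These rates hold only for the planted mix, as the adjusted threshold depends on how many genes change and how strongly. In the real libraries DDIT3, at a log2 fold change of −0.68, had a limma adjusted p of 0.118. The site step was tested on 11809 genes with a planted 7-mer of shift −0.1, which it placed at rank 1 with a recovered shift of −0.097. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the site search, tables and plots.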

Results

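The series asks how miR-409-3p acts on palmitate-treated endothelial cells, with DNAJB9 and p38 MAPK named in its title. HUVECs transfected with a miR-409-3p mimic (3 libraries) or a non-specific control (3 libraries), all given palmitate, were compared by RNA-seq at 13537 genes with a mean of at least 1 TPM. No untreated cells were analysed here, so each difference is between mimic and control cells that both received palmitate. The depth of each library is unknown in TPM. Relative to control 1, depth stood at 1.4 in control 2, 1.44 in control 3, 1.35 in mimic 1, 1.06 in mimic 2 and 1.12 in mimic 3, and differences within the deeper class (control 2, control 3, mimic 1) and the shallower class (control 1, mimic 2, mimic 3) are given beside the pooled ones. Between libraries, Pearson correlations of log2(TPM + 1) over genes ran from 0.9851 to 0.9912.

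DNAJB9, which encodes an endoplasmic reticulum (ER) co-chaperone (ENSG00000128590, chromosome 7, 108569568 to 108574850, plus strand, GRCh38), stood at 182 ± 14.6 TPM in the control and 132 ± 24.5 TPM in the mimic libraries (SD, n = 3 each). Its log2 fold change was −0.47 ± 0.12 (SE), and all mimic libraries (161, 117 and 119 TPM) lay below all control libraries (175, 199 and 172 TPM). Among the ER chaperones and ATF6/XBP1 targets, genes of protein folding and quality control in the ER, DNAJB9 fell together with SELENOK, SDF2L1, MANF, HERPUD1, SEC61B, HSPA5 and DERL2, so 8 of 26 tested members fell, 0 rose and 18 did not pass (limma, adjusted over the list alone). HSPA5, the main ER chaperone of the HSP70 family, moved from 4388 ± 418 to 3378 ± 448 TPM, and SDF2L1 from 222 ± 19.5 to 166 ± 15.7 TPM. Adjusted over all genes, 0 members passed in limma, although 10 were lower and 0 higher at an unadjusted p under 0.05; for DNAJB9 the limma adjusted p was 0.0286 over the list alone and 0.123 over all genes. The median of the list lay −0.24 from that of all genes (camera, adjusted p = 4.71e-10; adjusted p = 0.464 with an estimated correlation), and −0.15 in the deeper and −0.22 in the shallower class. Within those classes the DNAJB9 difference was −0.20 and −0.57. The count over the list alone was 0 without control 2, 1 without mimic 2 and 0 without mimic 3. For DNAJB9 the limma adjusted p over all genes ran from 0.00118 with library quality weights, the only setting that took it past the threshold, to 0.415 without mimic 3. Those weights rest mostly on control 2 and mimic 3.

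The genes of the ATF4/CHOP integrated stress response, a program of transcription and amino acid metabolism switched on by ER stress and amino acid shortage, had negative log2 fold changes in 21 of 23 tested members. DDIT3, which encodes the transcription factor CHOP, moved from 320.1 ± 32 to 199.7 ± 12.8 TPM (log2 fold change −0.68 ± 0.084), with differences of −0.62 in both depth classes. Of 23 tested members 12 fell, 0 rose and 11 did not pass (limma, adjusted over the list alone), against 0 adjusted over all genes in limma and 14 lower at an unadjusted p under 0.05. The 12 were DDIT3, NUPR1, CHAC1, ATF3, PPP1R15A, SLC3A2, SESN2, STC2, TRIB3, ASNS, CEBPB and ATF4. ATF3, a transcription factor induced by stress, stood at 64.6 ± 6.23 and 45 ± 7.6 TPM, and CHAC1, which degrades glutathione, at 45.9 ± 3.11 and 36.2 ± 1.16 TPM. The list median lay −0.34 from that of all genes (camera, adjusted p = 3.12e-15; adjusted p = 0.464 with an estimated correlation), −0.23 in the deeper and −0.32 in the shallower class. The count of members that fell was 4 without control 1, 3 without control 2, 3 without mimic 2 and 2 without mimic 3.

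Of the inflammatory genes of activated endothelium, 17 of 22 tested members had negative and 5 positive log2 fold changes. CXCL8, the neutrophil chemokine interleukin 8, moved from 470 ± 70.9 to 299 ± 81 TPM (log2 fold change −0.67 ± 0.18), CXCL1 from 339 ± 50.4 to 224 ± 46.2 TPM, CXCL2 from 68 ± 7.8 to 42.3 ± 13 TPM and IL6 from 74.4 ± 16.3 to 43.1 ± 15.8 TPM. Together with IL1A these made 5 of 22 tested members that fell, 0 that rose and 17 that did not pass (limma, adjusted over the list alone), with 0 over all genes in limma and 9 lower at an unadjusted p under 0.05. The adhesion molecule ICAM1 had a log2 fold change of −0.38 ± 0.14, with a limma adjusted p of 0.0753 over the list. The list median lay −0.33 from that of all genes (camera, adjusted p = 6e-10; adjusted p = 0.464 with an estimated correlation), −0.15 in the deeper and −0.46 in the shallower class. For CXCL8 the class differences were −0.26 and −0.85. The count over the list alone was 0 without control 2, control 3, mimic 2 or mimic 3, 12 without mimic 1, and 1 lower with 1 higher without control 1. It was also 0 with the length trend removed, where the list median still lay −0.35 from that of all genes. With median-ratio scaling it was 11, with quantile normalization 10 and with the GC trend removed 12, all lower.

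Log2 fold changes were positive in 24 of 25 tested genes of endothelial identity and in 31 of 35 of angiogenesis. Most tested genes were positive too: of the 9143 genes with no miR-409-3p site, 26.7% were negative. KDR, the main VEGF receptor of endothelial cells, moved from 215 ± 21.3 to 286 ± 11.6 TPM (log2 fold change 0.41 ± 0.079), PECAM1, an adhesion molecule of endothelial junctions, from 789 ± 72.3 to 981 ± 30 TPM, and VWF, the clotting factor stored by endothelium, from 604 ± 94.2 to 822 ± 82.8 TPM. The transcription factors ERG (143 ± 2.81 to 169.9 ± 2.45 TPM), FLI1, TAL1, SOX7 and SOX18 were among the 14 of 25 identity genes that rose, with 0 that fell and 11 that did not pass (limma, adjusted over the list alone). Of 35 angiogenesis and tip cell genes 16 rose, 0 fell and 19 did not pass (limma, adjusted over the list alone), among them CXCR4, EFNB2, DLL4, NOTCH1, NRP1, ANGPT2 and ACVRL1. EFNB2, a marker of arterial endothelium, moved from 69.4 ± 12.9 to 101.6 ± 6.23 TPM. Adjusted over all genes limma passed 0 members of either list, with 17 identity and 19 angiogenesis genes higher at an unadjusted p under 0.05. The medians lay 0.18 from that of all genes for identity (camera, adjusted p = 2.6e-06; adjusted p = 0.601 with an estimated correlation) and 0.12 for angiogenesis (camera, adjusted p = 1.93e-05; adjusted p = 0.601 with an estimated correlation). In the deeper and shallower class they lay 0.19 and 0.089 away for identity, and 0.12 and 0.12 for angiogenesis. KDR, TEK, TIE1 and ROBO4 stand on both the identity and the angiogenesis list, so the results of these lists are not independent. LYVE1 and VWF also stand on more than 1 of the lists. The identity count was 22 without control 1, 8 without control 2, mimic 2 or mimic 3, 9 without control 3 and 6 with the length trend removed, while the angiogenesis count was 0 without control 2, control 3, mimic 2 or mimic 3, with median-ratio scaling or with the length trend removed. The medians relative to all genes changed little there. With the length trend removed they were 0.193 for identity and 0.125 for angiogenesis, and with median-ratio scaling 0.11 for angiogenesis. The score of the identity list per library, unlike those of the other 8 lists past camera, overlapped between the groups through control 1 (0.043, against 0.025 in mimic 1; exact permutation p = 0.2).

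Of the 5 tested lymphatic endothelial markers, LYVE1, NRP2 and FLT4 rose, 0 fell and 2 did not pass (limma, adjusted over the list alone; 0 over all genes). LYVE1, a hyaluronan receptor, stood at 14.8 ± 2.75 and 22.3 ± 1.91 TPM. Camera gave an adjusted p of 0.0863 for this list, and adjusted p = 0.464 with an estimated correlation. LYVE1 is also on the identity list, and NRP2 and FLT4 are on the angiogenesis list. The count over the list alone was 1 without control 2, and the list passed camera without control 3 (adjusted p = 0.0173).

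**Figure D1:**
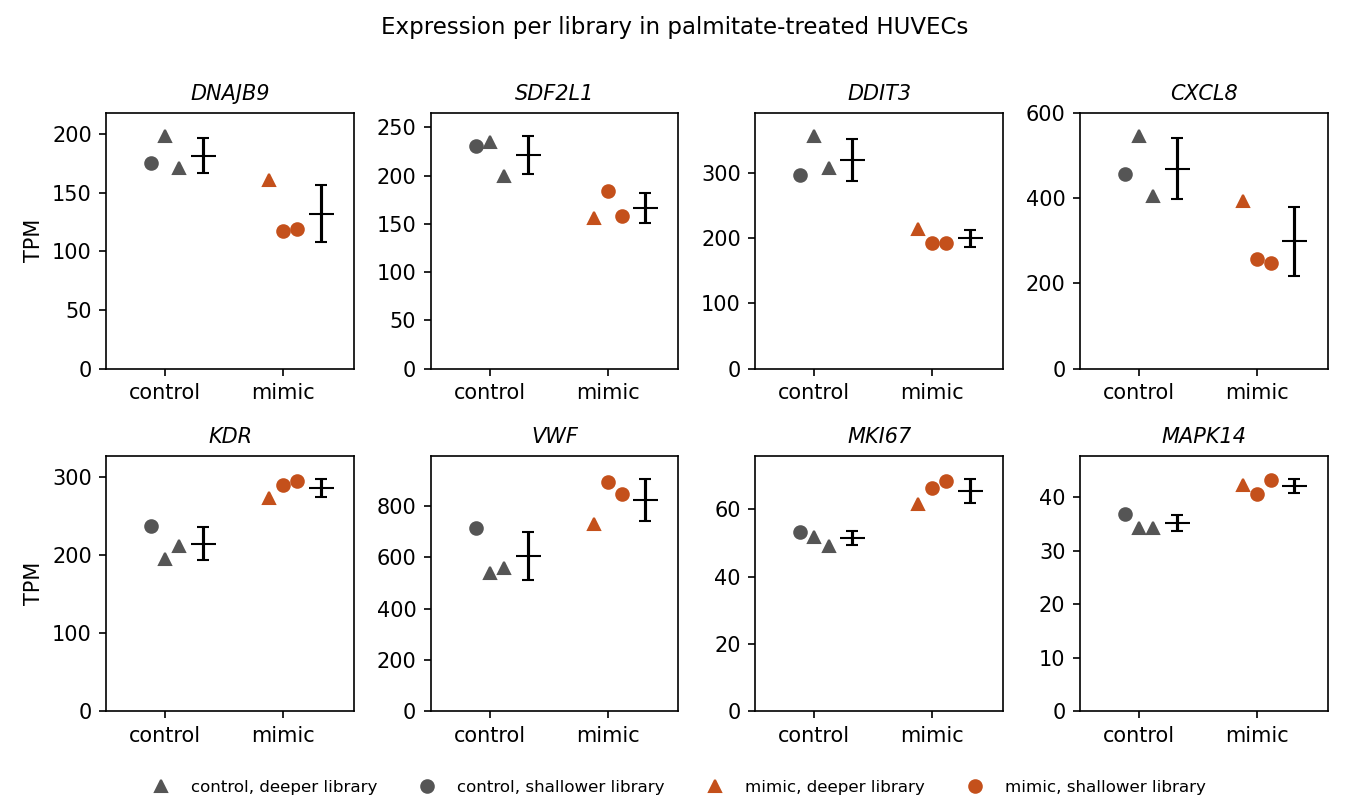
Expression in TPM (vertical axes, from 0) of DNAJB9, SDF2L1, DDIT3, CXCL8, KDR, VWF, MKI67 and MAPK14 in each control (grey) and mimic (orange) library, with triangles for the deeper and circles for the shallower depth class, and bars for the mean ± SD of 3 libraries. For each gene shown the mimic libraries lie on one side of the control libraries, as for DNAJB9 with means of 182 TPM in the control and 132 TPM in the mimic libraries. Apart from DNAJB9 and MAPK14, fixed by name, the genes are among those of smallest p in a list, so this follows largely from their choice. Of all tested genes, 28% do not overlap.

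Of 39 tested cell cycle genes, 38 had positive log2 fold changes, in data where most tested genes were positive. MKI67, a marker of dividing cells, moved from 51.4 ± 2.15 to 65.5 ± 3.55 TPM (log2 fold change 0.34 ± 0.064), TOP2A, a DNA topoisomerase of dividing cells, from 159.9 ± 5.4 to 194 ± 10.5 TPM, and CCNB1, the mitotic cyclin B1, from 153 ± 1.76 to 181 ± 5.5 TPM. KIF20A, the replication helicase genes MCM2 to MCM7 and E2F1 were among the 28 of 39 members that rose, with 0 that fell and 11 that did not pass (limma, adjusted over the list alone), against 0 over all genes in limma and 30 higher at an unadjusted p under 0.05. The list median lay 0.14 from that of all genes (camera, adjusted p = 2.75e-09; adjusted p = 0.503 with an estimated correlation), 0.079 in the deeper and 0.17 in the shallower class. The count over the list alone was 18 without control 2, 16 without control 3 and 0 without mimic 3, 15 with the length trend removed, and 0 with median-ratio scaling, both of which take the median of all genes to near 0.

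The ribosomal protein genes had a median −0.27 from that of all genes (camera, adjusted p = 6.08e-18; adjusted p = 0.464 with an estimated correlation). The difference was −0.47 in the deeper and −0.061 in the shallower class. RPS27 stood at 2509 ± 957 and 1398 ± 36.4 TPM and RPL11 at 1573 ± 95.2 and 1287 ± 9.32 TPM. Ribosomal protein genes took 8.52%, 9.48% and 10.9% of all TPM in control 1, 2 and 3, and 7.8%, 8.24% and 8.24% in mimic 1, 2 and 3. Adjusted over the list alone, limma passed 0 of 33 members, and 0 over all genes, with 15 lower at an unadjusted p under 0.05; without control 1 it passed 16 over the list.

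Genes of the NRF2 and oxidative stress list had a median −0.18 from that of all genes (camera, adjusted p = 2.33e-07; adjusted p = 0.464 with an estimated correlation), −0.17 in the deeper and −0.14 in the shallower class. HMOX1, the inducible haem oxygenase, stood at 621 ± 78.9 and 466 ± 30.2 TPM, and the ferritin chains FTH1 at 3646 ± 205 and 3137 ± 52.9 TPM and FTL at 6452 ± 213 and 5600 ± 207 TPM. Limma passed 0 of 22 members adjusted over the list alone and 0 over all genes; for HMOX1 the limma adjusted p was 0.0769 over the list and 0.118 over all genes. The count over the list alone was 1 lower without control 3 and 2 lower without mimic 1. It was 14 lower with median-ratio scaling and 17 lower with the GC trend removed.

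Of the 13 tested genes of small-RNA machinery, DICER1, which cuts microRNA precursors, and AGO1, which holds the mature microRNA, rose, 0 fell and 11 did not pass (limma, adjusted over the list alone; 0 over all genes). DICER1 moved from 19.7 ± 0.896 to 24 ± 1.3 TPM and AGO1 from 8.76 ± 0.801 to 10.9 ± 0.172 TPM. The list median lay 0.058 from that of all genes (camera, adjusted p = 0.0413; adjusted p = 0.7 with an estimated correlation), 0.065 in the deeper and 0.071 in the shallower class. The camera call held in 6 of 18 other settings, and was lost without control 1 (adjusted p = 0.0675), without control 3 (0.0678), without mimic 1 (0.0773) and without mimic 3 (0.0934). Over the list alone 0 members passed without any one library other than control 1.

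The p38 MAPK pathway list gave no camera call (adjusted p = 0.668; adjusted p = 0.943 with an estimated correlation). Log2 fold changes were positive in 25 of 30 members and negative in 5, and the list median lay 0.033 from that of all genes. MAPK14, which encodes p38α, moved from 35.1 ± 1.52 to 42.1 ± 1.32 TPM (log2 fold change 0.26 ± 0.059), and MEF2C, a transcription factor that p38 phosphorylates, from 32.4 ± 0.375 to 43 ± 2.56 TPM. GADD45A, a stress gene that activates a kinase upstream of p38, moved from 275 ± 7.77 to 229 ± 16.5 TPM. These made 2 of 30 members that rose, 1 that fell and 27 that did not pass (limma, adjusted over the list alone), with 0 over all genes. The list counts transcripts and says nothing of p38 phosphorylation. The counts over the list alone were 1 higher and 0 lower without control 2, control 3, mimic 2 or mimic 3, and 1 higher and 1 lower without mimic 1; with the length trend removed they were 0 and 0.

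Of the genes fixed by name besides DNAJB9 and MAPK14, MAP4K3 had a log2 fold change of 0.15 ± 0.058 (limma adjusted p = 0.193), PGF of 0.17 ± 0.084 (0.274) and ZEB1 of 0.067 ± 0.061 (0.529). ZEB1 turned to −0.03 with median-ratio scaling and −0.053 with the length trend removed.

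**Figure D2:**
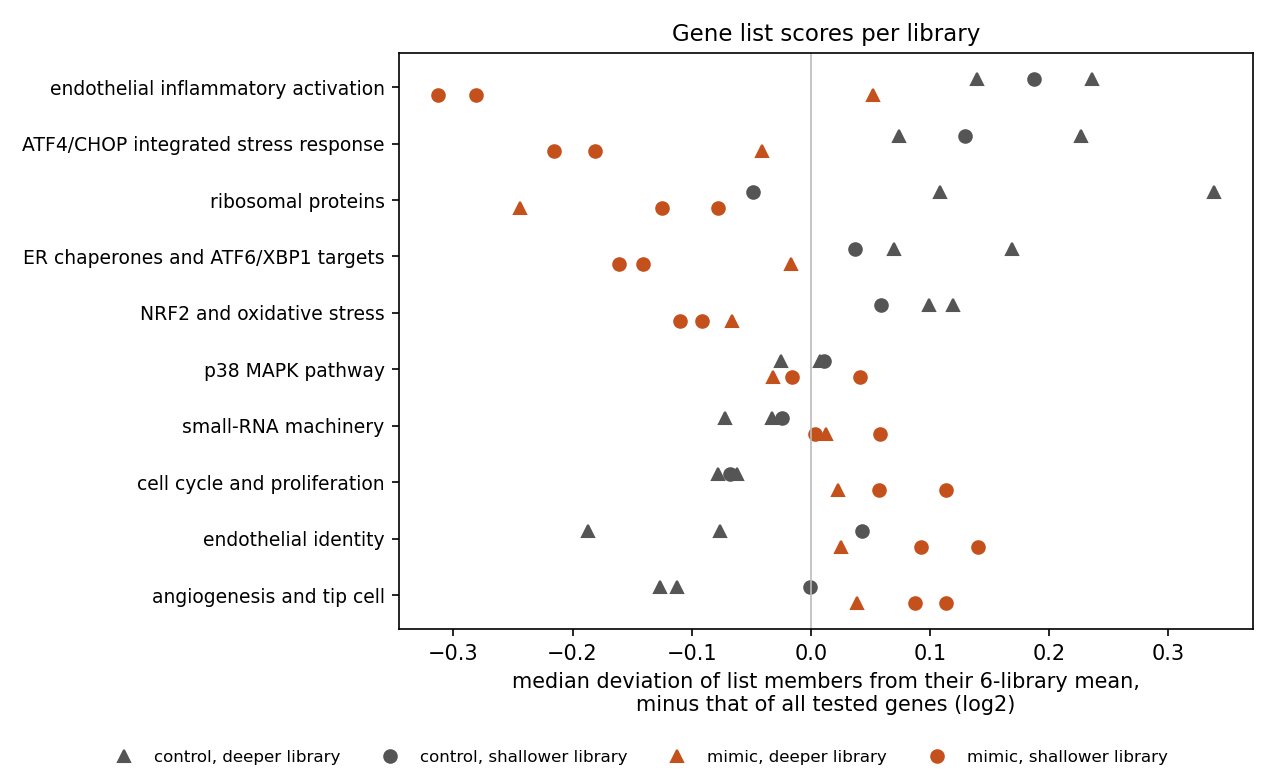
Score of each list per library (log2 units, the median deviation of its members from their gene means less that of all tested genes) for the 9 lists past the camera threshold and the p38 MAPK list, with control and mimic libraries in separate colours. Control and mimic libraries do not overlap in 8 of these 9 lists, which were selected on the same group difference. The same holds for 12 of all 21 tested lists. Chance gives 10% on average over splits, but the lists are not independent, so a single split can lie far from it. In the endothelial identity list control 1, at 0.043, lies among the mimic libraries.

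The other lists gave no camera call. For interferon response genes the adjusted p was 0.0804, and adjusted p = 0.7 with an estimated correlation. ISG15, a ubiquitin-like protein induced by interferon, stood at 74.6 ± 16.1 and 59.5 ± 7.76 TPM, and 0 of 23 members passed in limma adjusted over the list alone, with 1 at an unadjusted p under 0.05. The interferon list passed camera without control 2 (adjusted p = 0.000549) and without mimic 2 (0.00555). Among p53 targets and apoptosis genes (camera, adjusted p = 0.999) TP53INP1 rose from 36.7 ± 0.695 to 44.2 ± 0.607 TPM as 1 of 27 members, 0 fell and 26 did not pass (limma, adjusted over the list alone; 0 over all genes). That count was 6 without control 1 and 0 without any one of the other libraries. The median of the p53 list lay −0.011 from that of all genes, while camera gave it an upward direction. Camera gave adjusted p-values of 0.365 for fatty acid handling, 0.394 for autophagy and lysosome, 0.42 for vasomotor and haemostasis, 0.493 for mitochondrially encoded genes, 0.702 for cholesterol synthesis and SREBP2 and 0.702 for endothelial-mesenchymal transition. In these 6 lists 0 members passed in limma adjusted over the list alone. Without control 1 that count was 5 for fatty acid handling, 5 for autophagy and lysosome, 6 for vasomotor and haemostasis, 3 for cholesterol synthesis and 4 for endothelial-mesenchymal transition, each higher, and without mimic 1 it was 2 higher and 1 lower for vasomotor and haemostasis. CPT1A, which brings fatty acids into mitochondria, stood at 96.7 ± 7.95 and 119 ± 6.7 TPM, CAV1, the coat protein of caveolae, at 942 ± 47.5 and 1152 ± 56.3 TPM, and TGFBR2 at 449.8 ± 23.6 and 525 ± 4.63 TPM. Markers of smooth muscle, pericytes and fibroblasts (6 tested, camera adjusted p = 0.999) and of epithelium and trophoblast (7 tested, 0.42) also had 0 members passing over the list. Of the blood cell markers CD68 alone was tested, at 20.3 ± 2.1 and 20.2 ± 2.92 TPM.

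Over all genes, limma called 0 genes higher and 0 lower, with a smallest adjusted p of 0.108, that of the read-through gene PEDS1-UBE2V1, listed at 0 in all control libraries. At an unadjusted p under 0.05, 2578 genes were higher and 513 lower, a share of 83.4% higher among 3091. That total was 4688 without control 1, 1955 without control 2, 2058 without control 3 and 1618 without mimic 3. The share higher was 45.1% with median-ratio scaling (1140 higher, 1386 lower), 55.8% with quantile normalization (1378 and 1090), 71.7% with the libraries rescaled without genes above 1000 TPM (1991 and 787), 50.3% with the length trend removed and 49.9% with the GC trend removed. Median-ratio scaling, quantile normalization and removal of either trend centre the libraries on each other, so a nearly even share follows from their construction. The median log2 fold change of all tested genes was 0.087, 0.12 in the deeper and 0.027 in the shallower class, and 0.0502 without control 3. In 3193 genes (23.6%) all mimic libraries lay above all control libraries and in 596 (4.4%) below, 28% in all, where chance gives 10% on average over splits. Genes are not independent replicates, so a single split can lie far from that average, and the excess does not exclude chance. Without control 1, limma called 1724 genes higher and 252 lower; without mimic 3 it called 1 higher, and without any one of the other 4 libraries 0 in either direction. Control 1 stood apart from the other controls on the first principal component, the axis of largest spread between libraries (36.5%). It lay at −5.11, near mimic 1 at −4.69, with control 2 at 15.5 and control 3 at 23.8. On the second component (19.6%) control 1 lay at −21.5, apart from both groups. Control 2 and 3 lay there at −4.54 and 7.55, and mimic 1, 2 and 3 at 6.43, 10.7 and 1.34. With library quality weights estimated from these data limma called 4690 higher and 1399 lower, but those weights rest mostly on control 2 and mimic 3.

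Among genes with a mean above 19.7 TPM, the median of the tested genes, and with non-overlapping groups, the 10 higher genes of smallest p were ANGPTL2, CYYR1, MEF2C, ATP2B4, GINS1, CHSY1, ANP32A, LPCAT2, PPP1R16B and MTUS1. ANGPTL2, a secreted angiopoietin-like protein, stood at 24 ± 0.724 and 34 ± 1.47 TPM (log2 fold change 0.49 ± 0.061), CYYR1 at 27.3 ± 2.81 and 41.9 ± 0.621 TPM, ATP2B4, a calcium pump of the plasma membrane, at 35.1 ± 4.08 and 52.5 ± 2.84 TPM, and PPP1R16B at 46.5 ± 6.25 and 70 ± 3.39 TPM. The 10 lower genes of smallest p among them were DDIT3, ZFAND2A, SRA1, SNHG32, GOT1, SEC11C, CHAC1, BLVRB, SELENOK and SELENOM. ZFAND2A stood at 52.8 ± 4.61 and 38 ± 2.14 TPM, GOT1, the cytosolic aspartate aminotransferase, at 122.7 ± 7.49 and 95.5 ± 4.06 TPM, and SEC11C, a subunit of the signal peptidase of the ER, at 46.9 ± 4.8 and 33.8 ± 2.79 TPM. The limma adjusted p of each of these 20 genes was 0.118, so none passed over all genes.

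MicroRNAs act on mRNAs mainly through pairing of their seed with sites in the 3′ UTR. The annotated 3′ UTR of DNAJB9 (1497 nt) holds 2 sites of the 7mer-m8 type, CAACATT, at UTR positions 162 and 1009. On chromosome 7 (GRCh38, plus strand) they lie at 108573515 to 108573521, in the sequence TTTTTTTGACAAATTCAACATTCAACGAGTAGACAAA (108573500 to 108573536), and at 108574362 to 108574368, in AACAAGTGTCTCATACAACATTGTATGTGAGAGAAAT (108574347 to 108574383). SEC61B, a translocon subunit, was the only other of the 26 ER genes with such a site, and both fell over that list (log2 fold change −0.47 for DNAJB9 and −0.44 for SEC61B). CXCL1 and CXCL2, of the inflammatory genes that fell, also have one. Sites were present as well in genes that rose over their lists: TAL1, PECAM1 and MMRN2 of endothelial identity, and TOP2A, BIRC5 and RRM2 of the cell cycle. Of the integrated stress response genes PSAT1 and SLC7A11 have a site, and neither passed.

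Across the 11809 tested genes with an annotated 3′ UTR, the 1553 with an 8mer or 7mer-m8 site had a median log2 fold change 0.0099 above that of the 9143 with no site (95% bootstrap interval 0.0012 to 0.018). Camera in limma placed the site genes upward (p = 0.0277; p = 0.645 with an estimated correlation). Genes with a site had longer 3′ UTRs, with a median of 3212 nt against 1024 nt, and within 20 bins of 3′ UTR length the shift turned to −0.021 (bootstrap interval −0.03 to −0.012). Matched in this way the shift was −0.027 for 8mer, −0.018 for 7mer-m8 and −0.016 for 7mer-A1 sites. Of 14105 other 7-mers, the 5th and the 95th percentile of the matched shift were −0.023 and 0.032, and that of miR-409-3p lay between them, at percentile 7.56. The unmatched shift was also below 0 without control 1 (−0.01), without mimic 1 (−0.0094), with library quality weights (−0.011) and with the length trend removed (−0.014). It was larger without control 2 (0.0227), control 3 (0.0169) or mimic 2 (0.0305), with the depth class as a term (0.0289) and with the GC trend removed (0.0295).

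**Figure D3:**
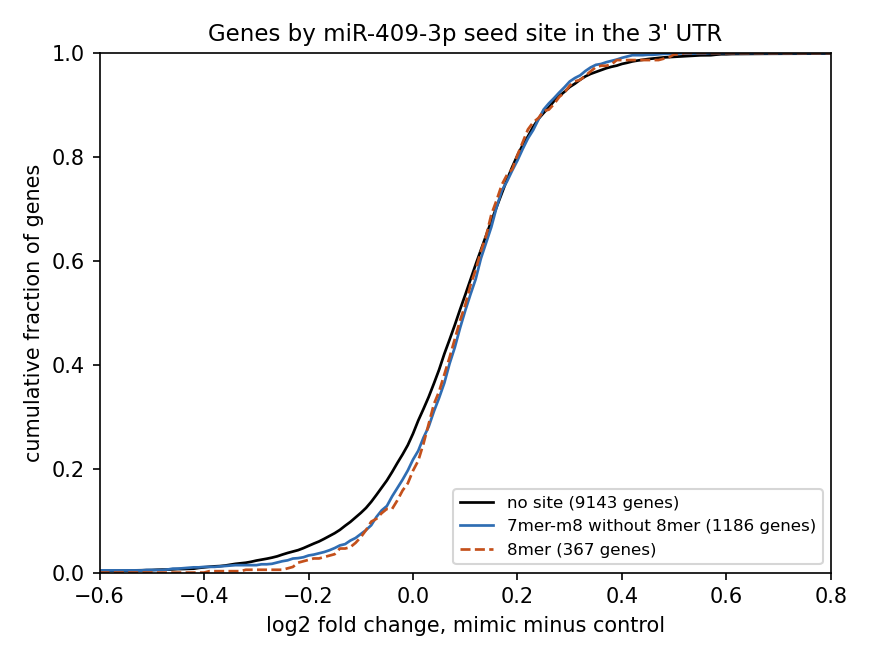
Cumulative share of genes (vertical axis) by log2 fold change, mimic minus control (horizontal axis), for genes with no miR-409-3p site in the 3′ UTR (9143 genes), with a 7mer-m8 site (1186) and with an 8mer site (367). The medians are 0.088, 0.098 and 0.093, and the shares of negative genes are 26.7%, 21.8% and 19.6%.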

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

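The depth class as a term, removal of the length or GC trend and rescaling without genes above 1000 TPM were tests chosen only after the results were seen; the other alternatives were planned. The planned count-based fits were not run, because the values are TPM, which carry no read totals; depth limits the low genes in an unknown way. Beside 0 genes higher and 0 lower in limma, 1 was higher with a pseudocount of 0.1, 1 higher and 3 lower with the replicate block, and 4690 higher and 1399 lower with library quality weights. Leaving out 1 library gave 0 to 1724 higher and 0 to 252 lower, with 1724 and 252 without control 1 and 1 higher without mimic 3. The weights were 0.296 for control 1, 6.09 for control 2, 0.346 for control 3, 0.691 for mimic 1, 0.747 for mimic 2 and 3.1 for mimic 3. Control 2 and mimic 3 thus carried most of the weight of their groups, so the weighted calls rest mainly on these libraries. The fit without control 1 and the weighted fit both called 1975 genes, 99.9% of the calls made without control 1. In 1976 and 6081 of their calls the direction was that of all 6 libraries. Both fits reuse the libraries of the main fit, so this agreement follows largely from shared data. The cause of the added calls was not tested. All other settings gave 0 and 0. The few calls, named after their values were seen, were PEDS1-UBE2V1 (higher) and, lower with the block, H4C11, ENSG00000285565 and ENSG00000260772. Same-numbered libraries had deviations correlated at −0.18, −0.14 and −0.05, and none correlated best with its own number. These values gave no sign of pairing, but with 3 libraries per group they cannot exclude a shared culture or day.

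DNAJB9 kept its direction in all 18 settings, from −0.65 with library quality weights (limma adjusted p = 0.00118) to −0.382 with the depth class as a term. As its groups do not overlap, leaving out a library could not change that direction. Without 1 library it ran from −0.614 to −0.387. Its adjusted p ranged up to 0.415. Of 104 genes that the fixed rule names, 100 kept their sign in all 18 settings, and CD68, KRT18, RGS5 and ZEB1 did not. Most were named for a small p, many with non-overlapping groups, so a kept sign follows largely from how they were picked. Past the threshold over all genes were 65 of them without control 1 and 95 with the weights.

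Beside 9 lists in camera, 0 passed with an estimated correlation (smallest adjusted p 0.464) and 0 in fry (0.117). Without 1 library 8 to 10 lists passed. In all 18 settings 8 of the 9 kept direction and threshold, and small-RNA machinery kept them in 6. Interferon response passed also with quantile normalization (adjusted p = 0.0369) and the depth class as a term (0.0488), lymphatic markers in 6 settings, and autophagy and lysosome with the length trend removed (0.0402). The mitochondrially encoded list turned upward, to 0.0997, with quantile normalization (adjusted p = 0.049); the cause was not tested. Counts adjusted over the list alone, both directions together, ranged from 0 to 16 for ER chaperones, 2 to 19 for the integrated stress response, 0 to 16 for inflammatory activation, 6 to 23 for identity, 0 to 30 for angiogenesis and 0 to 33 for cell cycle. With library quality weights the angiogenesis count was 27 higher and 3 lower, and the inflammatory count 15 lower and 1 higher. With the replicate block the counts were 0 for cell cycle, 3 for angiogenesis and 8, all lower, for ribosomal proteins.

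The site shift of 0.00992 kept its direction but missed the camera threshold with a filter at 10 TPM (0.0138), median-ratio scaling (0.0112), quantile normalization (0.00788), the replicate block (0.00992) and rescaling without abundant genes (0.0112). It turned negative with library quality weights (−0.0111), the length trend removed (−0.0135) and matching on 3′ UTR length (−0.0208). Without 1 library it ran from −0.0102 (without control 1) to 0.0305 (without mimic 2), and was −0.0094 without mimic 1. It was larger with the depth class as a term (0.0289), the GC trend removed (0.0295) and without control 2 (0.0227) or control 3 (0.0169), and smaller for 8mer sites alone (0.00471). The cause of these changes was not tested.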

Other observations

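The use of the planned median-ratio scaling as a test, the tests of gene families, of genes above 1000 TPM, of length and GC trends, of depth class and of other splits, and the bootstrap intervals of the site shift, were chosen only after the results were seen. The 28 families were written down after the gene values had been looked at, and 20 passed camera, 14 of them in the same direction with the length trend removed, but 0 with an estimated correlation (smallest adjusted p = 0.202). As the values were known when the families were picked, their camera p-values below describe these libraries and carry little weight as tests.

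Metallothioneins, small proteins that bind zinc and copper, had lower means with the mimic in all 6 tested members. MT2A stood at 4084 ± 970 TPM in the control and 2463 ± 180 TPM in the mimic libraries, and MT1E at 276 ± 51.8 and 178 ± 10.6 TPM. Their median log2 fold change was −0.57 (camera, adjusted p = 1.45e-08; adjusted p = 0.202 with an estimated correlation), with differences from all genes of −0.80 in the deeper and −0.37 in the shallower class. These genes are near-identical copies on chromosome 16, so single members are uncertain. Subunits of the ER translocon and signal peptidase, which bring proteins into the ER, were negative in 14 of 15 (−0.13 from all genes; camera, adjusted p = 8.41e-06; adjusted p = 0.202 with an estimated correlation), −0.15 and −0.12 in the classes.

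Semaphorins and plexins, guidance ligands and their receptors, were positive in 19 of 21 (0.17 from all genes, most of which were positive; camera, adjusted p = 0.0111; adjusted p = 0.576 with an estimated correlation), 0.18 in the deeper and 0.059 in the shallower class. PLXND1 stood at 212 ± 35.9 and 287 ± 24.2 TPM and SEMA4C at 6.67 ± 1.36 and 10.4 ± 1.06 TPM. Nuclear-encoded subunits of oxidative phosphorylation had a median −0.24 from all genes (73 tested; camera, adjusted p = 2.03e-16; adjusted p = 0.402 with an estimated correlation), −0.44 in the deeper and −0.0085 in the shallower class. PEDS1-UBE2V1, a read-through gene that overlaps PEDS1 and UBE2V1 on chromosome 20, was listed at 0 in all 3 control libraries and at 7.80, 12.2 and 4.19 TPM in mimic 1, 2 and 3, while UBE2V1 stood at 292 ± 14.1 and 302 ± 7.43 TPM. Reads of such overlapping genes cannot be told apart by their totals.

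More genes were higher than lower at an unadjusted p under 0.05 (2578 against 513, 83.4%). Median-ratio scaling took the share to 45.1%, but it sets the median of all genes near 0 by construction, so it cannot tell whether scaling is the cause. Rescaling without the 123 genes above 1000 TPM, which took 31.7%, 33.3% and 35.2% of TPM in control 1, 2 and 3 and 31.9%, 31.4% and 30.9% in mimic 1, 2 and 3, left 71.7%, between the outcomes set for either answer, so these genes may account for part of the excess. Log2 fold changes were also higher in longer genes (Spearman 0.258 over genes, which are not independent replicates), from a median of −0.0083 in the shortest to 0.13 in the longest of 5 bins. A technical shift between libraries and an effect of the mimic on total mRNA cannot be told apart here, because TPM fixes the total.

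For the 9 lists past camera, a length or a GC trend between libraries as the whole cause is argued against by 88.9% (8 of 9) kept with the length trend removed and 88.9% (8 of 9) with the GC trend removed. The exception in both was the small-RNA list, whose median difference from all genes went from 0.0576 (adjusted p = 0.0413) to 0.0292 with the length trend removed (0.44), a smaller difference, and to 0.0684 with the GC trend removed (0.0671), where the cause was not tested. Camera at its preset correlation also passed lists in other splits of the libraries, so a kept threshold alone is weak evidence. The medians of the kept lists held most of their size. With the length trend removed the NRF2 median shrank most, from −0.182 to −0.139. With the GC trend removed the identity median shrank most, from 0.181 to 0.164. Depth class as the whole cause is argued against by 88.9% (8 of 9) kept with the class as a term, where the small-RNA list again was lost (0.0469, camera adjusted p = 0.0593). The medians of all kept lists moved toward that of all genes with the term. They went from −0.338 to −0.28 for the integrated stress response, −0.238 to −0.198 for ER chaperones, 0.181 to 0.152 for identity and −0.182 to −0.149 for NRF2. The ribosomal protein difference was −0.262 (−0.274 without the term). As the term averages the within-class differences, −0.47 and −0.061 for this list, that value does not show that the classes were alike. A part played by length, GC content or depth stays open, as does a difference between the libraries that arose by chance. A state shared by the libraries of a group, such as culture density or the level of palmitate stress, was not tested and stays open. So does an action of the mimic.

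Splitting the 6 libraries in 10 ways is too few for a share under 0.05. Genes past the adjusted threshold numbered 0 in the study's split and at most 3 in another, and as a count of 0 is reached by all 10 splits by construction, it says nothing of chance. At an unadjusted p under 0.05 the study's split gave 3091, the only 1 of 10 that large, and the highest other gave 2059, which was the split by depth class. Lists past camera numbered 9, with 12 as the highest other and 4 of 10 splits as large, among them the split by depth class with 9. The split by depth class thus gave as many lists as the study's own, and of the 9 lists the within-class values lay farthest apart for ribosomal proteins, at −0.47 and −0.061.

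Pairing of the mimic's seed with 3′ UTR sites might lower site genes, but the shift was 0.00992 before and −0.0208 after matching on 3′ UTR length. The matched shift was more negative for 8mer (−0.0269) than for 7mer-m8 (−0.0182) and 7mer-A1 sites (−0.0162). Seed pairing predicts this order, but the classes have no intervals of their own. For all site genes the shift lay between the 5th and the 95th percentile of other 7-mers (−0.023 and 0.032). Before the test was run, that outcome had been set as counting against seed pairing and for 3′ UTR length. The bootstrap interval of this shift, −0.0298 to −0.012, was chosen after the results were seen and spans the 5th percentile. The value thus met the outcome set against seed pairing, but too narrowly to settle it. Length of the 3′ UTR and base composition stay open for the same reason: the shift was at percentile 7.56 of all 7-mers (interval 1.1 to 23.8) and 17.7 of 209 with the same bases (interval 0.478 to 70.8). DNAJB9, with 2 sites, had a log2 fold change of −0.47, but its list also holds lower genes without a site, so its value cannot be assigned to pairing.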
